A study of Homo sapiens with 18 samples.

How the data were processed

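Messenger RNA of normal human bronchial epithelial cells (NHBE), primary cells of the lining of the large airways grown in culture, was measured on 18 single-channel microarrays. The cells had been exposed to cigarette smoke for 15 min or to mock treatment and were collected 4 h or 24 h later. The labels name 2 experiments, SE68 with 10 arrays and SE76 with 8 arrays. Each of the 8 groups formed by experiment, treatment and time holds 2 or 3 arrays, so each arm has 4 arrays at 4 h and 5 arrays at 24 h. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

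The deposited table holds a linear intensity for each of 22272 probes on each array. The array platform, the scanner and the way the authors scaled the values are not given in the sources used here, and no genome build is given, so genes are named by symbol without coordinates. On each array between 23.86% and 43.79% of probes share that array's lowest value, a tiny constant that stands in place of a measurement, which left 12519 to 16957 measured probes per array. No pair of arrays held identical values. A set of 751 probes, none of them annotated, carried a single shared value on each array, and 3373 probes sat at the lowest value on every array. The number of arrays limits the precision of every value.

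The highest and lowest trimmed array means differed by 1.384 times, above the limit of 1.2 set for accepting the deposited scaling, so arrays were quantile normalized. Values below a floor were raised to it before the log2 step. The floor was planned as the 20th percentile of the values; read over all values this percentile is 3.46e-05, which lies among the constants, so the 20th percentile of measured values, 0.4277 (log2 −1.23), was used. That reading was settled before any test was run, and the other reading was tried as an alternative. Where only the lower arm of a gene had values at the floor its change is understated, a difference between 2 changes can move either way, and where all arrays of an arm lay at the floor the change is given as a lower bound.

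Of the probes, 16743 matched a single gene, 50 matched several and 5479 matched none. Of 14669 gene symbols, 1691 had several probes, and the probe with the highest mean was taken. A gene was tested when its normalized value lay above the median of all values, 0.4653, on at least 4 arrays. This left 10011 genes, of which 3224 had a geometric mean intensity above 2 and are called bright here. Genes of the X-inactivation and Y-linked classes were left out of the tables.

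Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). A single model with a mean for each arm and a term for experiment had 13 residual degrees of freedom and 9.05 prior degrees of freedom. It gave the effect of smoke at 4 h and at 24 h, the difference between these effects, and the change from 4 h to 24 h in mock cells. A model with a mean for each of the 8 groups gave the effects within each experiment and the test of their difference. Values of p were adjusted by the Benjamini-Hochberg method, and a gene was called below an adjusted p of 0.05. Adjusted p-values in the text come from limma.

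The comparisons, 26 gene lists and the alternatives, apart from those named in the closing section as added later, were set before the data were examined. Lists covered stress pathways, growth, airway cell types, markers of fibroblasts, leukocytes and endothelium, and genes of general cell upkeep. They were tested with camera from limma at its preset correlation, then with a correlation estimated from the data, and with fry. Genes named in the text follow a rule: the 10 largest rises and 10 largest falls among called genes with the same sign in both experiments for each smoke effect, the 4 largest changes in each direction for the difference between times and for mock cells, and up to 4 list members with the smallest p. Names outside this rule are marked as chosen after their values were seen. The test of the mock time course on the lists was added after seeing the data.

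The method was tested on simulated data with the same 18-array layout, in which 9819 genes passed the filter. Planted changes of log2 1, 2 and 3 were recovered in 25.8%, 46.2% and 65.2% of genes at 4 h, with 1 false call among 90. The same sizes were recovered in 26.6%, 60.9% and 66.7% at 24 h, with 4 false calls among 104. With nothing planted, 0 of 9857 genes were called by limma. The simulated noise was drawn independently for each gene and array, without correlation between genes or deviant arrays. These rates of false calls therefore need not hold for the real arrays.

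Alternatives covered the deposited scaling, centring of arrays, a pseudocount of 1 without a floor, a floor at the 40th percentile, other filters, all probes or their mean, other model terms, each experiment alone and each array left out in turn. Whether replicate numbers pair arrays is not known. After group means were removed, 1 of 9 pairs sharing a number correlated above 0.1 (range −0.257 to 0.148). In groups of 2 arrays the deviations mirror each other, so both pairs must give the same value, and this check cannot decide the question. Python 3.11.15 and matplotlib 3.10.9 drew the plots.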

Results

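Gene expression was recorded in cultured bronchial epithelial cells 4 h and 24 h after a 15 min exposure to cigarette smoke or after mock treatment. Each arm held 4 arrays at 4 h and 5 arrays at 24 h, drawn from experiments SE68 and SE76. Across the 18 arrays, 12519 to 16957 of 22272 probes gave a measured value, and 10011 genes were tested. Arrays of the same group correlated at 0.788 to 0.924 across genes, lowest between the SE68 mock arrays at 4 h. Replicate 1 of these had a median correlation of 0.785 with the other SE68 arrays, the lowest such value of any array, and replicate 2 had 0.868. Fits without replicate 2 kept replicate 1 as the only SE68 mock array at 4 h. Changes below are log2 differences of normalized intensity, smoke minus mock, with the standard error (SE) of the fit.

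The comparison at 4 h asks which transcripts had moved soon after the exposure. HMOX1, heme oxygenase 1, which breaks down heme, rose 59.7-fold (5.90 ± 0.26 SE, n = 4 arrays per arm, adjusted p = 9.96e-13), from a geometric mean intensity of 1.12 to 67.1. HSPA1A, an inducible chaperone of the heat shock response, rose 24.6-fold from 3.4 to 83.7 (4.62 ± 0.255 SE, adjusted p = 4.9e-11). TXNRD1, a thioredoxin reductase, rose 7.64-fold, and PTGS2, the inducible cyclooxygenase that starts prostaglandin synthesis, rose 6.27-fold (adjusted p = 1.39e-07 and 2.17e-09). The rises were present in each experiment: HMOX1 rose by 5.93 in SE68 and 5.86 in SE76, HSPA1A by 4.49 and 4.75, TXNRD1 by 2.31 and 3.56, and PTGS2 by 2.87 and 2.43.

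The other large rises at 4 h belonged to SRXN1, the sulfiredoxin that restores oxidised peroxiredoxins (3.71), PRDM1, a transcriptional repressor (3.18), IER5 (3.09), PPP1R15A, which directs the dephosphorylation of the translation factor eIF2 (2.90), and GCLC, the catalytic subunit of the enzyme that begins glutathione synthesis (2.73). Their adjusted p-values lay between 2e-07 for PPP1R15A and 0.00259 for PRDM1. DLX2, a homeobox transcription factor, was at the floor on all mock arrays at 4 h and was at least 6.57-fold higher after smoke. The largest falls were smaller than the largest rises. PLCL2 fell by 2.34 (adjusted p = 0.00132) and STAT4, a transcription factor of cytokine signalling, fell by 1.36 (adjusted p = 0.00478), and both kept their calls when any single array was left out. KIAA1614 (−1.83), DOC2A (−1.76), H6PD (−1.75), CUZD1 (−1.62), NUTM1 (−1.55), PROM1 (−1.54), ANKS1B (−1.48) and IDS (−1.35) also fell, with adjusted p from 0.0247 to 0.0435, and each lost its call in 4 to 12 of the 18 fits that left out a single array. With the deposited scaling the calls of KIAA1614, CUZD1, PROM1, ANKS1B and IDS were lost as well.

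**Figure D1:**
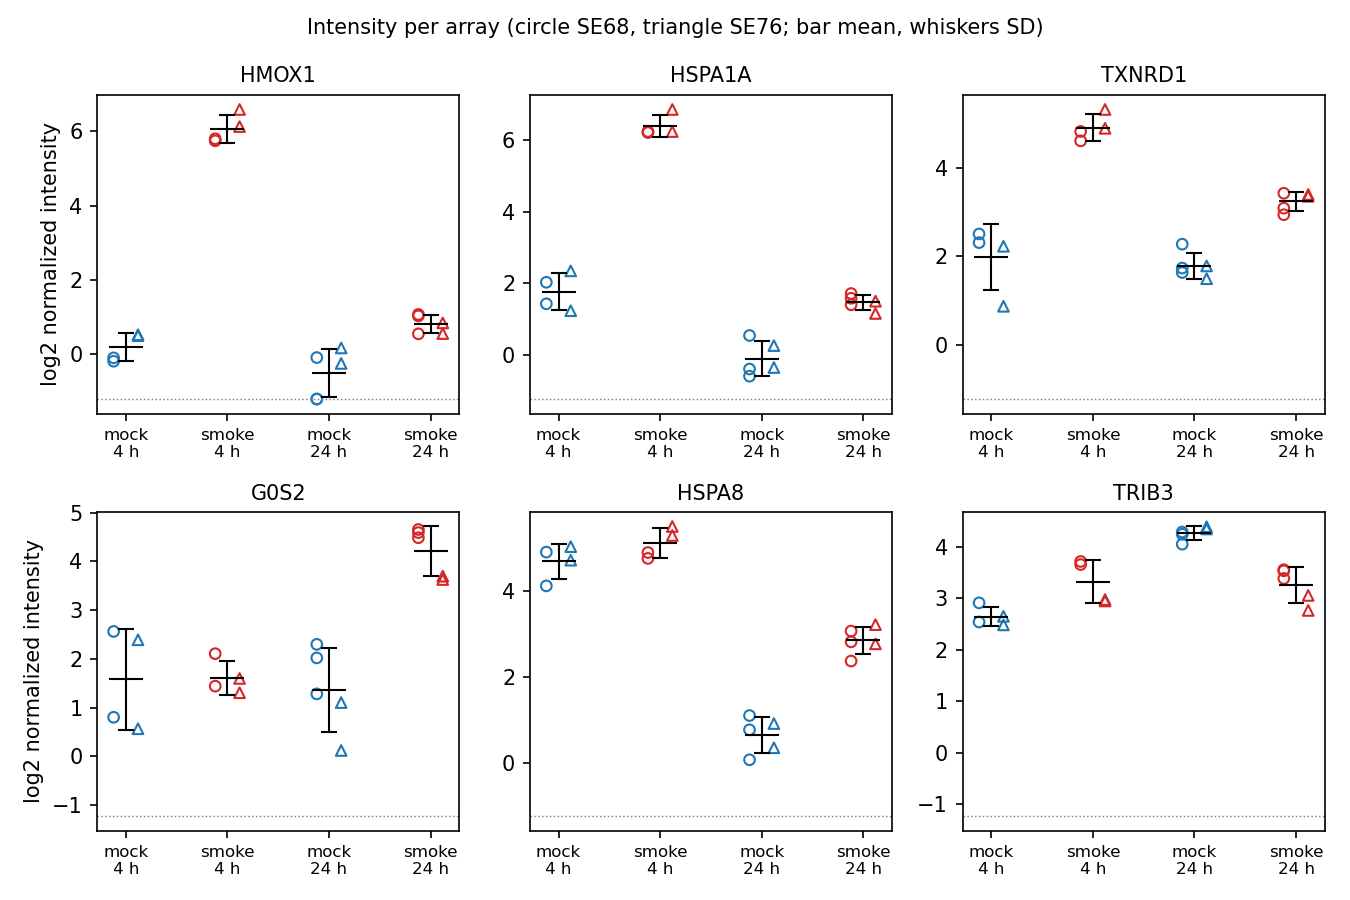
Log2 normalized intensity of 6 genes on each array, by treatment and time; circles are SE68, triangles SE76, bars are arm means, whiskers SD, and the dotted line is the floor at −1.23. HMOX1 lay between 5.75 and 6.59 on the 4 smoke arrays at 4 h and at or below 0.51 on the mock arrays of that time.

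Of 26 fixed gene lists, 10 moved at 4 h by camera, all 10 upward, and 4 of these calls held with an estimated correlation. Targets of NRF2, the transcription factor that drives antioxidant and glutathione genes, led them. Of 26 tested members 15 rose and 0 fell, or 20 and 0 adjusted over the list alone, with a median change of 1.15 (adjusted p = 2.84e-28, and 0.00127 with an estimated correlation). Besides HMOX1, TXNRD1 and SRXN1 they included SQSTM1, an autophagy receptor (1.59). Among 21 cytosolic heat shock genes 7 rose and 0 fell, or 9 and 1 adjusted over the list alone (median 0.69, adjusted p = 1.55e-11, and 0.00127 with an estimated correlation). These included the cochaperones DNAJB1 (2.12), BAG3 (1.83) and HSPH1 (1.32). Of 25 targets of p53, the transcription factor activated by DNA damage, 3 rose and 0 fell, the same numbers adjusted over the list alone. They were the cell cycle inhibitor CDKN1A (2.08), GADD45A (1.49) and the kinase PLK2 (1.64), and the list's median was 0.41 (adjusted p = 8.68e-05, and 0.00303 with an estimated correlation). Of 25 immediate early and AP-1 genes, which respond fast to growth and stress signals, 6 rose and 0 fell, or 10 and 0 adjusted over the list alone (median 0.12, adjusted p = 8.68e-05, and 0.00312 with an estimated correlation). Besides IER5 they included the phosphatase DUSP6 (1.07), CCN1 (1.43) and ZFP36, an RNA-destabilising protein, which was at the floor on all mock arrays and at least 2.79-fold higher.

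The other 6 list calls at 4 h were lost with an estimated correlation. Of 20 genes of ATF4 and the integrated stress response, a pathway that answers amino acid shortage and misfolded protein, 3 rose and 0 fell, or 4 and 1 adjusted over the list alone. The 3 were PPP1R15A, the cystine transporter SLC7A11 (1.26) and TRIB3 (0.68), and the list had a median of 0.06 (adjusted p = 0.00956, and adjusted p = 0.133 with an estimated correlation). Endoplasmic reticulum chaperones had a median of 0.49, with 1 of 19 members called, PDIA4 (1.75), and 2 adjusted over the list alone (adjusted p = 0.000393, and adjusted p = 0.197 with an estimated correlation). Cholesterol synthesis and uptake had a median of 0.31, with 1 of 17 called, INSIG1 (1.08), and 4 adjusted over the list alone (adjusted p = 0.000181, and adjusted p = 0.197 with an estimated correlation). Proteasome subunits had a median of 0.30, with 1 of 23 called, PSMB5 (1.85), and 8 adjusted over the list alone (adjusted p = 4.16e-06, and adjusted p = 0.197 with an estimated correlation). In oxidative phosphorylation limma called 0 of 24 genes over all genes and adjusted over the list alone, with 7 at unadjusted p under 0.05 (median 0.31, adjusted p = 0.00018, and adjusted p = 0.315 with an estimated correlation). In DNA replication and S phase limma called 0 of 23 both ways, with 5 at unadjusted p under 0.05, the median was −0.18 in SE68 and 0.45 in SE76, and the list's adjusted p of 0.0468 became adjusted p = 0.315 with an estimated correlation. The S phase call was also lost without SE76 mock 4 h replicate 1 (adjusted p = 0.32), SE68 mock or smoke 4 h replicate 1 (adjusted p = 0.0744 and 0.0755), SE76 smoke 4 h replicates 1 or 2 (adjusted p = 0.0802 and 0.0761) or SE76 mock 24 h replicate 2 (adjusted p = 0.0503). Among the genes named here, PDIA4 lost its call in 14 of the 18 fits without a single array, TRIB3 in 6, CCN1, ZFP36 and PSMB5 in 4, INSIG1 in 3 and DUSP6 in 1, and PDIA4, CCN1 and PSMB5 also lost theirs with the deposited scaling.

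The remaining 16 lists had no camera call at 4 h. Among 9 targets of the aryl hydrocarbon receptor, which senses smoke hydrocarbons, TIPARP (1.64, adjusted p = 0.000408) and the quinone reductase NQO1 (1.46, adjusted p = 0.0174) rose. NQO1 is also on the NRF2 list. Adjusted over the 9 receptor targets alone, 2 rose and 1 fell, and the median of this list was 0.02. Of the same list CYP1A1, AHRR and ALDH3A1, named after their values were seen, sat at the lowest value on all 18 arrays and were not tested. Among 25 inflammatory and NF-kB genes PTGS2 alone rose, over all genes and adjusted over the list alone (median 0.01). In the metallothioneins and zinc export list, MT1E fell by 0.70 and the other 3 members were not called (median −0.35). NQO1 lost its call in 3 of the 18 fits without a single array, and MT1E in 4 and with the deposited scaling. Medians of the other lists were 0.13 for mitosis, 0.60 for the 2 tested EGF receptor ligands, 0.12 for hypoxia and glycolysis, −0.10 for interferon-stimulated genes, 0.11 for squamous and 0.14 for basal cell genes. They were −0.15 for ciliated, 0.09 for secretory, −0.13 for fibroblast, 0.19 for leukocyte and −0.34 for endothelial markers, −0.09 for ribosomal proteins and 0.18 for reference housekeeping genes. In these 13 lists limma called 0 of 156 genes over all genes, with 19 at unadjusted p under 0.05; adjusted over the list alone 1 EGF receptor ligand and 1 hypoxia gene rose and 1 leukocyte marker fell. The leukocyte median was positive while its mean (−0.04) and test were negative, and the ribosomal median and test were negative while the mean was 0.01. The medians of the inflammatory, interferon and ribosomal lists changed sign between scalings.

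In all, limma called 131 genes at 4 h, 100 higher and 31 lower after smoke (1502 at unadjusted p under 0.05); 60 of the higher and 18 of the lower genes were bright. The count was 41 without the experiment term, 35 from the 4 h arrays alone, 12 in SE68 alone and 31 in SE76 alone, 53 with replicates as blocks, 67 with the floor read over all values and 87 without the intensity trend, and another split of the 8 arrays gave 231. It was 567 without SE68 mock replicate 2, 72 without SE68 mock replicate 1, 80 without SE68 smoke replicate 1, 56 without SE76 mock replicate 1 and 52 without SE76 smoke replicate 1. The number of lower genes was 6 and 8 in these last fits, without SE76 mock replicate 1 and SE76 smoke replicate 1, 19 and 20 without SE76 mock replicate 2 and SE76 smoke replicate 2, 14 with the deposited scaling and 18 without the filter on dim genes.

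The comparison at 24 h asks which changes were present a day after the exposure. GPX2, an epithelial glutathione peroxidase, rose 8.61-fold (3.11 ± 0.34 SE, n = 5 arrays per arm, adjusted p = 9.78e-06), from 0.671 to 5.78. G0S2, an inhibitor of the lipase that breaks down stored fat, rose 7.2-fold from 2.58 to 18.5 (2.85 ± 0.33 SE, adjusted p = 1.92e-05). HSPA8, the constitutive member of the same chaperone family as HSPA1A, was 2.20 higher than in mock cells (adjusted p = 5.73e-07), and FTL, the ferritin light chain that stores iron, was 2.16 higher (adjusted p = 2.53e-07). By experiment, GPX2 rose by 2.90 in SE68 and 3.42 in SE76, and G0S2 by 2.71 and 3.05. IL17RB, a receptor for an interleukin of the IL-17 family, fell by 2.10 (adjusted p = 0.000717), from 1.98 to 0.461, and PLIN2, a coat protein of lipid droplets, fell by 2.04 (adjusted p = 0.000236).

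Other large rises at 24 h were FAM83A (2.84), CDCP1 (2.79), PGD, an enzyme of the pentose phosphate pathway (2.67), TGFB1, a growth factor (2.59), FADS1, a fatty acid desaturase (2.52), DYNLRB1 (2.43) and HYPK (2.33), with adjusted p from 7.79e-05 to 0.0014. EMC7 was at the floor on all mock arrays and at least 5.36-fold higher. Other large falls were NUPR1, a stress-induced chromatin protein (−2.06), HOXD11 (−2.05), the chemokine CX3CL1 (−2.03), RELN (−1.98), the DNA repair gene FANCC (−1.93), TACR1, the substance P receptor (−1.91), and STRBP (−1.87), with adjusted p from 0.000935 to 0.0167. IHH, a hedgehog ligand, was at the floor on all smoke arrays and at least 4.08-fold lower. HOXD11 lost its call in 4 of the 18 fits without a single array, and STRBP turned to 0.30 with a pseudocount of 1 and to 0.92 with the floor read over all values, where another of its 3 probes was taken.

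By camera 6 lists moved at 24 h, 5 up and 1 down, and 2 of the calls held with an estimated correlation. Of 26 NRF2 targets 11 rose and 0 fell, or 18 and 1 adjusted over the list alone (median 0.81, adjusted p = 1e-16, and 0.0207 with an estimated correlation). Besides GPX2 and FTL they included SQSTM1 (1.51) and thioredoxin, TXN (0.93, both adjusted p = 1.55e-06). The median of these targets was 0.88 in SE68 and 0.81 in SE76. Genes of ATF4 and the integrated stress response moved down: 4 of 20 fell and 0 rose, the same numbers adjusted over the list alone (median −0.40, adjusted p = 3.2e-05, and 0.0207 with an estimated correlation). The 4 were the pseudokinase TRIB3 (−1.01), NUPR1, GARS1, a tRNA synthetase (−0.71), and DDIT3, the transcription factor CHOP, which was at the floor on all smoke arrays and at least 2.71-fold lower. The median of the ATF4 list was −0.26 in SE68 and −0.72 in SE76.

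The other 4 list calls at 24 h were lost with an estimated correlation. Of 21 heat shock genes 4 rose and 0 fell, or 8 and 4 adjusted over the list alone (median 0.35, adjusted p = 0.00252, and adjusted p = 0.103 with an estimated correlation). The 4 were HSPA8, HSPA1A (1.58), DNAJA1 (0.92) and DNAJB1 (0.66). Of 17 cholesterol genes 3 rose and 0 fell, or 6 and 0 adjusted over the list alone (median 0.55, adjusted p = 9.22e-06, and adjusted p = 0.135 with an estimated correlation). They were INSIG1 (1.42), IDI1 (1.44) and ACAT2 (0.85). Of 20 genes of hypoxia and glycolysis 4 rose and 0 fell, or 7 and 1 adjusted over the list alone (median 0.31, adjusted p = 0.00252, and adjusted p = 0.0603 with an estimated correlation). They were NDRG1 (0.95), ALDOC (1.63), P4HA1 (0.61) and TPI1 (0.41). Of 23 proteasome subunits 4 rose and 0 fell, or 5 and 0 adjusted over the list alone (median 0.31, adjusted p = 0.000586, and adjusted p = 0.422 with an estimated correlation). They were PSMA3 (2.07), PSMB5 (1.81), PSMD8 (1.62) and PSMB7 (0.80). Of the genes named here, P4HA1 lost its call in 13 of the 18 fits without a single array, ACAT2 in 8, ALDOC in 7 and TPI1 in 4.

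Single members changed at 24 h in several of the 20 lists without a camera call. Among 25 inflammatory genes IL1B (1.58, adjusted p = 3.03e-05) and the chemokine CCL20 (2.82-fold) rose and IL32 (−1.39) fell, or 2 and 2 adjusted over the list alone. Among 25 immediate early genes DUSP6 (1.22) and MYC (1.14) rose and DUSP5 (−0.99) and DUSP2 fell, DUSP2 at least 3.35-fold to the floor on all smoke arrays, or 6 and 3 adjusted over the list alone. The squamous marker IVL, involucrin, was at least 2.81-fold higher than mock arrays that all lay at the floor, while the keratins KRT16 (−0.75) and KRT14 (−0.61) fell and the basal gene LAMB3 rose (0.63). NQO1, which is also on the NRF2 list, rose by 1.53 among 9 aryl hydrocarbon receptor targets, where TIPARP was 0.55 (adjusted p = 0.147). PDIA4 rose (1.45), as did TFRC, the transferrin receptor, among 10 reference housekeeping genes (1.76). GADD45A (−0.71), MT1E (−0.61), TPX2 (−0.63) and DLGAP5 (−0.78) of mitosis, CHAF1B (−1.18) of S phase, CXCL11 (−1.24) of the interferon list and the ciliary gene CCDC39 (−0.86) fell. CDKN1A was 0.36 (adjusted p = 0.172). Of these calls, that of DLGAP5 was lost in 13 of the 18 fits without a single array, CHAF1B in 10, MYC in 9, IL32 in 8, DUSP5 in 7, PDIA4 and CCDC39 in 6, CCL20 and CXCL11 in 5 and KRT14 in 2, and CDKN1A was called in 1. The calls of IL32 and CXCL11 were also lost with the deposited scaling. CD68 rose among 6 leukocyte markers (1.38), a list with a median of −0.28. List medians were 0.13 for endoplasmic reticulum chaperones, −0.47 for metallothioneins, 0.35 for aryl hydrocarbon receptor targets, 0.16 for EGF receptor ligands and for immediate early genes, 0.08 for interferon, 0.20 for squamous, 0.22 for basal and −0.12 for ciliated genes. They were 0.14 for fibroblast and −0.37 for endothelial markers, 0.06 for ribosomal proteins, 0.13 for oxidative phosphorylation and 0.20 for housekeeping genes. For p53 targets (median −0.05, mean 0.02), mitosis (0.07 and −0.04), S phase (0.07 and −0.07), inflammatory (−0.03 and 0.10) and secretory genes (0.15 and −0.06) the median and mean differed in sign. The test for these lists took the sign of the mean except for p53 targets, and the p53 and inflammatory medians changed sign with the deposited scaling.

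In all, limma called 497 genes at 24 h, 250 higher and 247 lower (2005 at unadjusted p under 0.05); 106 of the higher and 66 of the lower genes were bright, so 181 of the 247 lower genes had a geometric mean intensity of 2 or less. The count was 167 without the experiment term, 54 in SE68 alone, 15 in SE76 alone, 165 with replicates as blocks and 205 with the floor read over all values. It was 263 without SE68 mock replicate 2, 318 without SE68 mock replicate 3, 306 and 285 without SE68 smoke replicates 1 and 2, 323 without SE76 mock replicate 1 and 289 without SE76 smoke replicate 1. Without SE68 smoke replicate 2 lower genes outnumbered higher ones, 173 to 112, and with the deposited scaling higher genes did, 238 to 168. Without SE68 mock replicate 1 there were 201 higher and 159 lower genes, and without SE76 smoke replicate 2 there were 189 and 145.

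**Figure D2:**
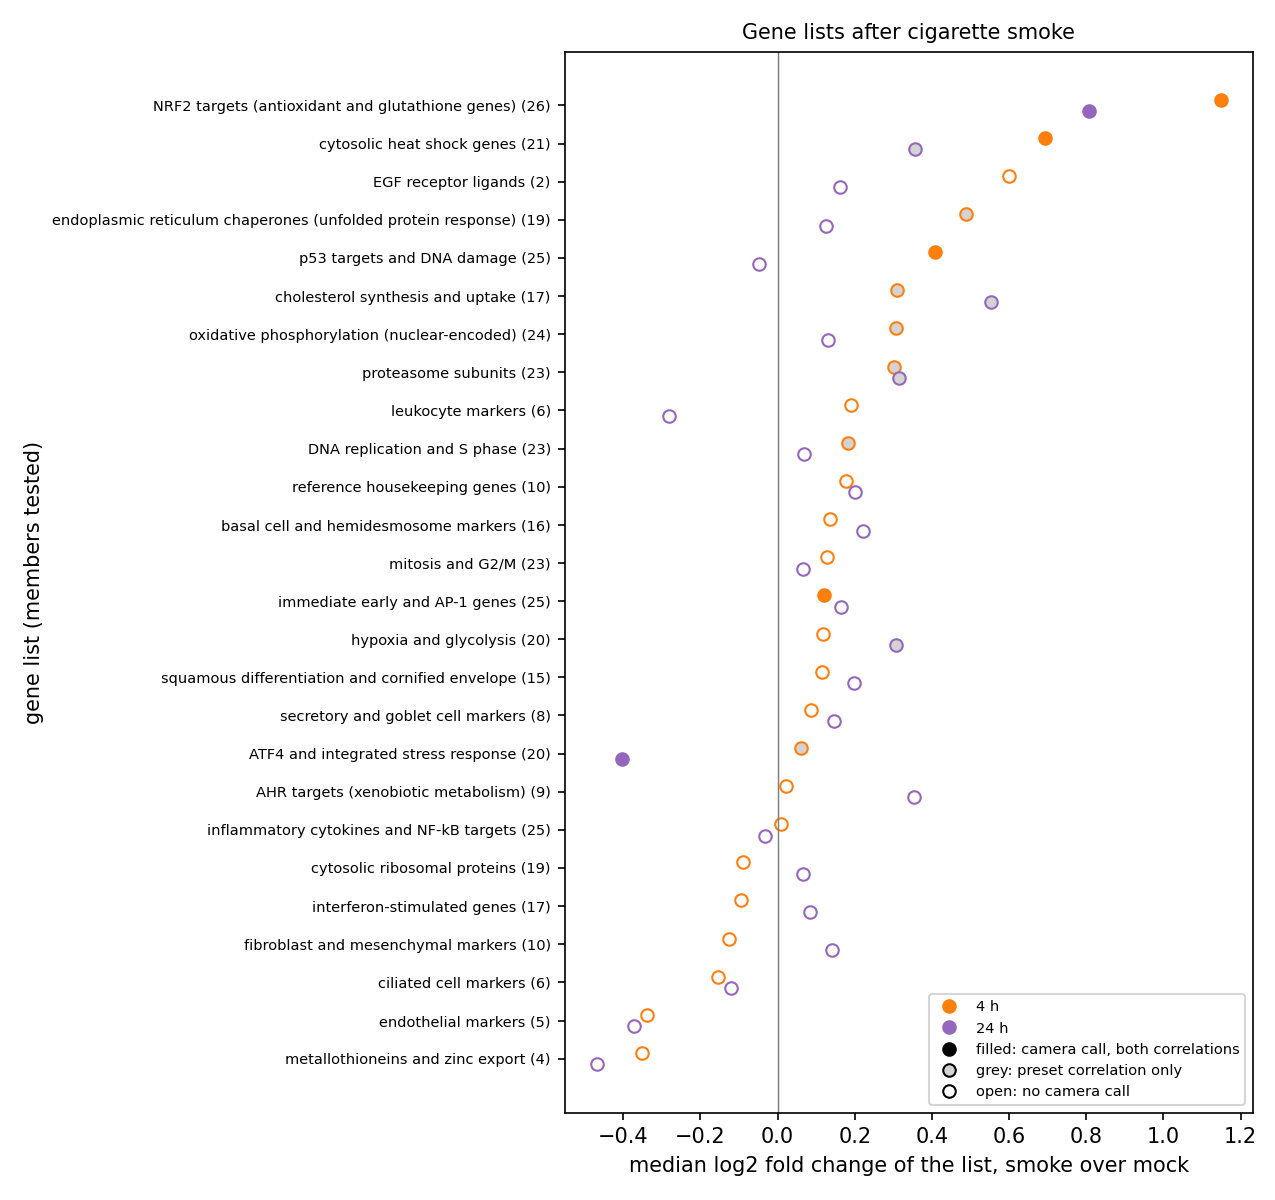
Median log2 fold change, smoke over mock, of 26 gene lists at 4 h (orange) and 24 h (purple), with the number of tested members in brackets; filled points have a camera call with both correlations, grey points with the preset correlation only, open points none. NRF2 targets had the highest median at both times (1.15 and 0.81), and the ATF4 list lay at 0.06 at 4 h and −0.40 at 24 h.

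More genes were called at both times than independent calls would give. The p-values of the overlap take genes and calls as independent. They are not, since both calls on a gene used the same estimate of its spread. Of 100 genes higher at 4 h and 250 higher at 24 h, 37 were shared against 2.5 expected (Fisher's exact test, p = 2.98e-34). They included HMOX1, HSPA1A, TXNRD1, NQO1, GPX2, FTL, TXN, SQSTM1, DLX2, PRDM1 and INSIG1. Among lower genes 6 were shared against 0.765 expected (Fisher's exact test, p = 9.31e-05), among them MT1E and ANKS1B. Another 4 genes went in opposite directions, and were picked out after their values were seen. TRIB3 (0.68 at 4 h, −1.01 at 24 h) and GADD45A (1.49 and −0.71) were higher and then lower than mock, and FGFBP1 (−0.72 and 0.42) and TUBB6 (−0.48 and 0.58), a tubulin, were lower and then higher.

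**Figure D3:**
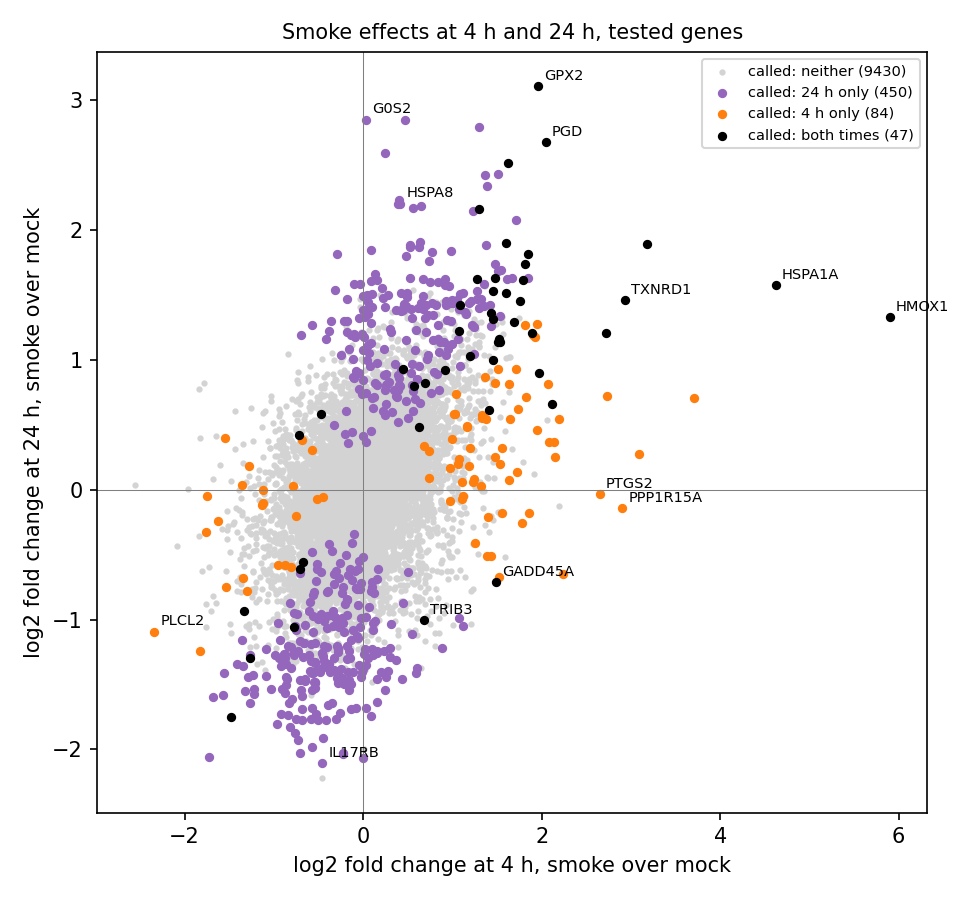
Log2 fold change of each tested gene, smoke over mock, at 4 h (horizontal) and 24 h (vertical); orange points are called at 4 h only (84), purple at 24 h only (450), black at both times (47), grey at neither (9430). HMOX1 and HSPA1A lie far to the right, with 24 h changes of 1.33 and 1.58.

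The test of the difference between the smoke effects, 24 h minus 4 h, called 34 genes, 10 with a higher effect at 24 h and 24 with a lower one (779 at unadjusted p under 0.05); without SE68 mock 4 h replicate 1 these were 21 and 26. The count was 16 without the experiment term, 5 in SE68 alone, 12 in SE76 alone and 82 with all probes one by one. The largest decline was in HMOX1, whose effect went from 5.90 to 1.33, a difference of −4.57 ± 0.35 SE (adjusted p = 7.85e-08). HSPA1A (−3.05 ± 0.34 SE, adjusted p = 2.35e-05), PPP1R15A (−3.04, adjusted p = 2.8e-05) and SRXN1 (−3.00, adjusted p = 0.00451) followed. The largest gains were in G0S2 (2.82 ± 0.49 SE, adjusted p = 0.00478), ALDH1A3, a retinaldehyde dehydrogenase (1.86, adjusted p = 0.000508), HSPA8 (1.78, adjusted p = 0.00213) and GPRC5A, an orphan receptor of airway epithelium (1.77, adjusted p = 0.038). HSPA8 changed in mock cells by −3.86 in SE68 and −4.23 in SE76 from 4 h to 24 h. Its gain is thus a smaller fall in smoke-exposed cells, not a rise. GPRC5A lost its call in 13 of the 18 fits without a single array, and SRXN1 turned to 0.59 with the floor read over all values.

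By camera 8 lists differed in their smoke effect between the times, 7 lower at 24 h and 1 higher, and 4 held with an estimated correlation. Of 20 ATF4 genes 4 had a lower effect and 0 a higher one, or 8 and 0 adjusted over the list alone (median −0.47, adjusted p = 1.23e-10, and 0.00128 with an estimated correlation). For 21 heat shock genes these numbers were 3 and 1, or 5 and 1 adjusted over the list alone (median −0.34, adjusted p = 0.000119, and 0.0246 with an estimated correlation). For 25 p53 targets they were 2 and 0, or 3 and 0 adjusted over the list alone (median −0.28, adjusted p = 0.000256, and 0.00588 with an estimated correlation). For 25 immediate early genes they were 3 and 0, or 6 and 1 adjusted over the list alone (median −0.18, adjusted p = 0.00681, and 0.0246 with an estimated correlation). In mock cells the ATF4 and p53 lists rose from 4 h to 24 h (medians 0.739 and 0.235) and heat shock genes fell (median −0.345). Lower effects of the ATF4 and p53 lists therefore need not be falls in smoke-exposed cells. Of 26 NRF2 targets 3 had a lower effect at 24 h and 0 a higher one, or 6 and 2 adjusted over the list alone. The NRF2 median was 0.01, and −0.10 with the deposited scaling, while the mean was −0.39 and the test pointed down (adjusted p = 0.0322, and adjusted p = 0.699 with an estimated correlation). S phase (median −0.25, adjusted p = 0.0294, and adjusted p = 0.464 with an estimated correlation), oxidative phosphorylation (−0.17, adjusted p = 0.0364, and adjusted p = 0.759 with an estimated correlation) and hypoxia genes (0.27, adjusted p = 0.0461, and adjusted p = 0.208 with an estimated correlation) had 0 members called by limma, with 3, 1 and 3 at unadjusted p under 0.05. In the 18 fits without a single array the hypoxia call was lost in 12, the NRF2 and oxidative phosphorylation calls in 8 each and the S phase call in 4, with adjusted p up to 0.139, 0.16, 0.562 and 0.178. The number of lists was 4 without SE68 mock 24 h replicate 1 or SE68 smoke 24 h replicate 3, and 5 without SE76 mock replicate 1 of either time.

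The comparison of mock cells at 24 h with those at 4 h gives the background against which both smoke effects were read. HSPA8 fell by 4.02 ± 0.21 SE (adjusted p = 2.28e-11), from a geometric mean intensity of 25.9 on 4 arrays to 1.57 on 5. HSPA1A fell by 1.86 (adjusted p = 0.000116), DKK1, a Wnt antagonist, by 1.52, and FST, follistatin, by 1.43 (adjusted p = 0.000569 and 2.55e-05). NUPR1 and DDIT4, a stress-induced inhibitor of mTOR signalling, were at the floor on all mock arrays at 4 h and reached 3.17 and 2.56 at 24 h (adjusted p = 5.22e-05 and 6.58e-05). The transcription factor CEBPD (2.21) and ASNS, asparagine synthetase (1.83), rose as well.

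Of 20 ATF4 genes 8 rose and 0 fell in mock cells over this time, or 12 and 0 adjusted over the list alone (median 0.74, adjusted p = 3.07e-18, and 7.68e-05 with an estimated correlation). Of 21 heat shock genes 5 fell and 0 rose, or 6 and 1 adjusted over the list alone (median −0.34, adjusted p = 2.93e-08, and 0.00463 with an estimated correlation). Of 25 p53 targets 2 rose and 0 fell, or 3 and 0 adjusted over the list alone (median 0.23, adjusted p = 0.00594, and 0.0245 with an estimated correlation). They were CDKN1A (1.54) and GADD45A (1.64), named after their values were seen. Basal cell genes (median 0.18, 1 of 16 called, 4 adjusted over the list alone; adjusted p = 0.00594, and adjusted p = 0.08 with an estimated correlation) and inflammatory genes (0.08, 2 of 25 called and 2 adjusted over the list alone; adjusted p = 0.0227, and adjusted p = 0.054 with an estimated correlation) moved up by the preset test. So did squamous genes (0.23, 2 of 15 called and 4 adjusted over the list alone; adjusted p = 0.0236, and adjusted p = 0.444 with an estimated correlation) and oxidative phosphorylation (0.31, 0 of 24 called by limma and 5 at unadjusted p under 0.05; adjusted p = 0.00115, and adjusted p = 0.444 with an estimated correlation). The inflammatory call was lost without SE68 mock 4 h replicate 2 (adjusted p = 0.163), and the oxidative phosphorylation and squamous calls without SE68 mock 4 h replicate 1 (adjusted p = 0.224 each). Oxidative phosphorylation also lost its call without SE76 mock 4 h replicate 1 (adjusted p = 0.0566), and the squamous list without SE76 mock 24 h replicates 1 or 2 (adjusted p = 0.124 and 0.144). Limma called 68 genes, 51 higher and 17 lower at 24 h (919 at unadjusted p under 0.05), and 120 without SE68 mock 4 h replicate 2, 105 higher and 15 lower. Without SE68 mock 4 h replicate 1 the numbers were nearly even, 32 higher and 28 lower. The count was 25 without the experiment term, 12 in SE68 alone, 13 in SE76 alone, 32 without the intensity trend and 106 with all probes one by one.

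The last comparison asks whether the smoke effects differed between the experiments. Within the model of 8 group means, 48 genes were called at 4 h in SE68 and 127 in SE76, and 241 and 77 at 24 h. Of these, 39 (81.2%) and 93 (73.2%) at 4 h, and 206 (85.5%) and 61 (79.2%) at 24 h, had the same sign in the other experiment. Across all tested genes, which are not independent replicates, the smoke effects of the experiments correlated at r = 0.0451 (Spearman's rho = −0.0157) at 4 h and r = 0.397 (rho = 0.385) at 24 h, and at 0.407 and 0.422 among bright genes. The effects at 4 h and 24 h correlated at r = 0.605 (rho = 0.627) within SE76 and r = 0.2 (rho = 0.163) within SE68, and at 0.491 and 0.423 among bright genes. The test of the difference called 0 genes with limma at each time, with 1657 and 747 at unadjusted p under 0.05 and smallest adjusted p of 0.146 and 0.0506. A floor at the 40th percentile gave 31 and 35 genes. At 4 h the count was 62 without SE68 mock 4 h replicate 2, 4 without SE68 mock 4 h replicate 1, 8 and 13 without SE68 smoke 4 h replicates 1 and 2, 4 and 30 without SE76 mock 4 h replicates 1 and 2, 14 without SE76 smoke 4 h replicate 1, and 2 without SE68 mock 24 h replicate 3. At 24 h it was 16 and 12 without SE76 smoke 24 h replicates 2 and 1, 6 and 10 without SE76 mock 24 h replicates 1 and 2, 4 without SE68 mock 24 h replicate 3, 3 without SE68 smoke 4 h replicate 1, and 1 without SE68 mock 24 h replicate 2 or either SE68 mock 4 h replicate.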

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

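The list tests and counts of label splits in this part were chosen before the result was seen, while the splits within each experiment and the look at probes without a gene name were added after.

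The smoke effect differed between 24 h and 4 h, by a test of the difference itself, for 34 genes. The named ones with a higher effect at 24 h were G0S2 (2.82), ALDH1A3 (1.86), HSPA8 (1.78) and GPRC5A (1.77), and those with a lower effect were HMOX1 (−4.57), HSPA1A (−3.05), PPP1R15A (−3.04) and SRXN1 (−3.00). HMOX1 and HSPA1A remained higher than mock at 24 h (1.33 and 1.58), whereas PPP1R15A was at −0.14. Gene lists with a different effect at the times, given as the median of 24 h minus 4 h, were ATF4 and integrated stress response (−0.47), cytosolic heat shock genes (−0.34), p53 targets (−0.28), DNA replication and S phase (−0.25), immediate early genes (−0.18), oxidative phosphorylation (−0.17), hypoxia and glycolysis (0.27) and NRF2 targets (0.0116). The NRF2 test pointed down, with a mean of −0.39, and the median was −0.10 with the deposited scaling. The calls of S phase, oxidative phosphorylation, hypoxia and NRF2 targets were lost with an estimated correlation. All these effects are relative to mock cells. In mock cells the ATF4 and p53 lists rose and heat shock genes, HSPA8 among them, fell over the same time.

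For smoke at 24 h, 1 of 100 splits, the real one, gave as many genes as 497, and the highest other split gave 6. With splits drawn only within each experiment it was 1 of 60, and the highest other gave 6. Chance in the placing of arrays can thus be excluded. The labels do not say whether replicates are separate cultures, so chance differences between cultures cannot be excluded. For smoke at 4 h, 2 of 35 splits gave at least 131 genes, and the highest other gave 231, so chance cannot be excluded by this count. That other split kept SE76 in order and exchanged a single array of each arm within SE68, so it still held part of the real contrast. Within the experiments there are 18 splits, too few for a share under 0.05, and the highest other again gave 231. Genes called in SE68 had the same sign in SE76 for 39 of 48 and those called in SE76 had the same sign in SE68 for 93 of 127 (binomial p = 1.52e-05 and 1.61e-07, with genes taken as independent, which they are not). The relabellings for the difference between times exchanged smoke and mock labels within each time. They stand for no smoke effect at all, not for an equal effect at both times, so they cannot exclude chance for the difference. Of 100 such splits, the real one included, 2 reached 34 genes, and the highest other gave 334. Within the experiments it was again 2 of 100, and the highest other gave 178. A count so far above the real one points to a structure of the samples. The relabelled arrays still held the real smoke effects, which may be part of it, and the source was not traced. For mock cells over time, 3 of 100 splits reached 68 genes. The highest other gave 536 and set the SE76 mock arrays with a single SE68 array against the rest, so 1 SE68 array stood against 4. These splits did not keep the experiments balanced, and so high a count points to a structure of the samples, so they do not settle chance. In splits within each experiment, which kept them balanced, 1 of 60, the real one, reached 68 genes and the highest other gave 21. By this later count chance in the placing of arrays can be excluded, with the same limit on cultures as for smoke at 24 h. Within SE68 and SE76 alone the mock count was 12 and 13.

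Probes without a gene name, outside every comparison above, also carried signal. Of 2745 such probes tested, 12 were higher and 3 lower after smoke at 4 h, and 35 were higher and 56 lower at 24 h.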

How the results depend on the processing

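The floor read over all values, the limit to bright genes and the list tests of mock time were chosen after seeing the data, and the other tests before. Of 119 results for named genes, 85 kept direction and side of the threshold in all 18 fits without a single array, and 20 did so in SE68 and SE76 alone. With the deposited scaling 108 of the 119 were the same. STRBP at 24 h reversed to 0.30 with log2(value + 1) and 0.92 with that floor, where another of its 3 probes was taken. SRXN1, 24 h minus 4 h, reversed to 0.59 with that floor, and the cause was not tested. Counts for smoke at 4 h (131), smoke at 24 h (497), their difference (34) and mock time (68) follow in that order where they moved over 1.5 times. Without the experiment term they were 41, 167, 16 and 25. SE68 alone gave 12, 54, 5 and 12, and SE76 alone 31, 15, 12 and 13; fewer arrays were used. An adjusted p below 0.01 left 49, 136 and, for mock time, 34. The replicate block, although it is not known whether the numbers pair arrays, gave 53 and 165 for the smoke effects. The floor over all values gave 67 and 205. Without the intensity trend 87 were left at 4 h and 32 for mock time. The arrays of 4 h alone gave 35, and bright genes alone 162 at 24 h (fewer genes tested). All probes gave 82 for the difference and 106 for mock time. The difference between experiments (0 and 0) gave 31 and 35 with the 40th percentile floor, 4 and 9 without a filter and 37 and 7 with the floor over all values. At 24 h it gave 1 with log2(value + 1), with the 60th percentile filter and with the mean of probes. List calls at an estimated correlation fell from 10, 6, 8 and 7 to 4, 2, 4 and 3, and fry, which compares a list with no other genes, passed 9, 10, 4 and 5. SE76 alone gave 6 lists at 4 h and 4 for the difference, and SE68 alone 4 for the difference and 4 for mock time. Except where fewer arrays or genes were used, the cause was not tested. Without single arrays the ranges were 52 to 567 at 4 h, 263 to 672 at 24 h, 29 to 47 for the difference, 50 to 120 for mock time, and 0 to 62 and 0 to 16 between experiments. Lists ranged 9 to 10, 6 to 6, 4 to 9 and 6 to 7. A group left with a single array was assumed to vary like the others. The test of RNA quality from control probe sets was not run, since no such sets were recognised in the table. Signal near background limits the dim genes; 23.86% or more of the probes of each array had no measured value.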

Other observations

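All tests in this part were chosen after the result was seen, except the floor test for dim genes and the scaling and normalization tests for SE76.

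Of the 247 genes lower at 24 h, 181 were dim. Array noise arising separately in each gene is argued against: of 97 dim genes called lower in SE68, 73 (75.3%, exact 95% interval 65.5 to 83.5) were also lower in SE76, against 48.5% of all 6787 dim genes (exact binomial p = 1.12e-07). The interval and p take genes as independent, which they are not. Noise that moves many dim probes together was not tested. The floor on low values stays open, since 55.8% of the dim genes (101 of 181, exact 95% interval 48.2 to 63.2) were still called with the floor at the 40th percentile. A biological explanation, a fall of weakly expressed transcripts a day after smoke, may hold for those seen in both experiments, and was not tested further.

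Smoke effects at 4 h and 24 h resembled each other more within SE76 (r = 0.605 across genes) than the 4 h effects of SE68 and SE76 did (r = 0.0451), a gap of 0.56. An intensity-dependent scaling is argued against, since r stayed at 0.598 after a trend on intensity was removed. The quantile normalization added here is argued against too, with r = 0.636 on the deposited scaling. The authors' own scaling was not tested. A background of dim probes may account for much of the gap, which was 0.0834 among bright genes (0.491 and 0.407). Separate processing of the SE76 mock and smoke arrays could also leave such a pattern, since r was 0.567 after the SE68 effects were removed. A response particular to the SE76 cells would give the same value, and the labels name no batches that would separate these, so both stay open. Before normalization, medians of measured values were 1.446 to 1.581 on SE76 mock arrays and 1.188 to 1.427 on SE76 smoke arrays. In SE68 these ranges overlapped (0.8992 to 1.136 and 0.9665 to 1.126). In SE76 at 24 h, 36.27% and 37.87% of probes lay at the lowest value in mock and 23.86% and 26.93% after smoke. At 4 h these shares were 31.73% and 31.05% in mock and 38.03% and 26.43% after smoke.

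Heat shock genes were higher at 4 h than at 24 h in mock cells. Whether the fall was confined to a deviant experiment could not be settled. In SE68 17 of 21 members were lower and in SE76 14 of 21, with medians of −0.375 and −0.23. By camera with an estimated correlation the list pointed down in both (unadjusted p = 0.00437 and 0.00184). After adjustment it passed in SE76 (adjusted p = 0.0239) and not in SE68 (adjusted p = 0.0569), which had the larger median fall. Arguing against this explanation required a pass in both experiments, so it stays open. A fault of the probe of HSPA8, the largest fall, is argued against by 4 other heat shock genes called lower. A passing stress of mock handling may be the source, but the immediate early list did not move with it (median 0.04, adjusted p = 0.444 with an estimated correlation), which leaves this open. A change with time in culture, the biological alternative, was not tested.

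A hypothesis for the ATF4 genes, lower after smoke at 24 h, is that their level relative to mock may reflect the rise of ATF4 genes over time in mock cells. The list's median rose by 0.74 in mock cells from 4 h to 24 h, and changed by 0.04 in smoke-exposed cells. Smoke-exposed cells at 24 h lay above mock cells at 4 h by a median of 0.45. These differences are sums of the contrasts already given, so they describe the pattern and do not test the hypothesis, which stays open.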
